A study of Caenorhabditis elegans with 6 samples.

How the data were processed

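The series measured RNA of whole Caenorhabditis elegans of the wild-type strain N2 at the late L4 to young adult stage. Per the labels' protocols, animals were kept for 5 hours in nematode growth medium buffer with heat-treated OP50, an Escherichia coli strain used as food, and received either 25 µM chaetocin or the vehicle DMSO. RNA was extracted with an RNAqueous-Micro kit and messenger RNA libraries were made with a SMARTer kit, per the labels' protocols. The 6 libraries fell into 2 groups of 3 by their treatment label, and the labels call the libraries of each group biological replicates 1 to 3. The labels do not say whether these came from separate cultures, so p-values measure the spread between these libraries.

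The authors deposited FPKM, fragment counts scaled by transcript length and library size, for 46926 genes and 60000 transcripts, with 1 column per library. The tables' names call them raw, but their values were read as FPKM. Columns summed to between 1232966 and 1326067 FPKM. The log2 ratio of the authors' mean normalized count to FPKM rose with log2 transcript length (r = 0.935 across 13007 genes, which are not independent). For all 46926 genes the transcript values summed to the gene value within 0.1 FPKM. Trimmomatic 0.36, FastQC 0.11.4, MultiQC, STAR 2.7.9a, RSEM 1.3.1 and the build WBcel235 are named per the submitters' processing notes, and the annotation release is not given in the sources used here. RSEM assigns fragments that match several transcripts by estimation, so near-identical genes and isoforms of 1 gene share fragments. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes are uncertain. All 46926 gene identifiers were found in the Ensembl annotation of WBcel235, from which positions and gene types were taken.

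A further table deposited by the authors holds their own comparison of 16062 coding genes: a log2 fold change of DMSO over chaetocin, its standard error on the log2 scale, a column headed as p-value and a mean normalized count. The Benjamini-Hochberg adjusted normal p of fold change over standard error had a median ratio of 0.9903 to the deposited p-value, so the deposited p-values were read as adjusted. The software behind this table is not given in the sources used here. Its sign was turned so that positive values mean higher with chaetocin.

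The tests planned before the data were examined needed counts, and the gene and transcript tables hold FPKM, so the planned count-based test and count-based alternative could not be run. The analysis used limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.1). Genes and transcripts with at least 0.5 FPKM in at least 3 libraries were kept. Libraries were scaled by an unweighted trimmed mean of log ratios, trimming 30% of the ratios and 5% of the means at each end, with factors between 0.9769 and 1.0271. The group difference was fitted with variance moderation along the mean level, and p-values, all 2-sided, were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Filter, pseudocount and scaling were set after the unit was known and after call counts under several pseudocounts and filters had been seen. A fold change on the log2(FPKM + 0.1) scale understates the change of genes with low values. Levels in the text are scaled FPKM as mean ± SD over 3 libraries, ratios are ratios of these means, and ± after a log2 fold change is its standard error. Where a gene was listed at 0 in a library, the value of each library is given.

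Depth per library is unknown, since no file holds counts per library and low FPKM values showed no whole-fragment steps, so no counting interval is given. A gene listed at 0 is not shown to be absent. The authors' mean normalized counts summed to 42874568 over their genes.

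The 44 gene lists were fixed before the data were examined, and 9 of their symbols had no match in the annotation. Each list was tested with camera (limma), which compares its members with all other genes, at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists. Beside it stood camera with an estimated correlation and fry, which asks whether the members move on balance in 1 direction. Genes named in the text follow a rule fixed beforehand. It takes the 10 genes with the largest fold change in each direction among those past the threshold with a mean of at least 1 FPKM (in place of the planned counts per library size) and no overlap between the groups. It adds up to 4 members with the smallest adjusted p in each list with a called member, and 25 fixed genes. Other genes named are said to have been chosen after their values were seen.

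The fitting functions were tested on simulated data with the real means and spreads and 50 changed features at each fold. Among 15213 genes, 46% of changes of 1.5-fold, 78% of 2-fold, 90% of 4-fold and 94% of 8-fold were recovered. In this 1 run 7.8% of the calls were false (13 of 167), against a nominal 5%, too few calls to tell these apart. Far fewer genes were changed than the 1286 called in the data, so the recovery shares may not hold there. Among 21002 transcripts the shares were 26%, 42%, 58% and 86%, with 6.2% false calls. Alternatives tried were median-of-ratios scaling and unscaled FPKM, no filter and a stricter filter of a mean of at least 5 FPKM, the replicate number or the title number as a block, leaving out each library, a fold threshold, the genes of the authors' deposited table alone, and the other list tests. Pseudocounts of 0.01, 0.5 and 1 and robust variance moderation were added after seeing the data. Transcript usage within genes was tested with limma. Permutations, Fisher's exact tests, binomial intervals and plots used Python 3.11.15, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.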

Results

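RNA of whole wild-type animals was compared after 5 hours in 25 µM chaetocin or in the vehicle DMSO, with 3 libraries each. Chaetocin is a fungal toxin used as an inhibitor of lysine methyltransferases. The comparison asks which transcripts differ after a short exposure. The gene and transcript tables hold FPKM and no counts, so depth per library is unknown. Between 18747 and 18933 genes were above 0 in each library. Ribosomal RNA took 1.586, 2.767 and 1.26% of FPKM in DMSO replicates 1 to 3, and 0.755, 4.129 and 1.037% in chaetocin replicates 1 to 3.

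Among the largest increases with chaetocin were those of the metal-induced gene numr-1 (9.48 ± 12.7 to 1728 ± 66.97 FPKM), comt-4 (22.4 ± 28.6 to 2242 ± 25.05) and the cytochrome P450 gene cyp-33C12 (1.44 ± 1.83 to 168 ± 2.52). The metallothionein genes mtl-1 and mtl-2 fell (1029 ± 62.2 to 283 ± 12.7 and 766 ± 25.4 to 135 ± 15.1 FPKM, mean ± SD, n = 3 each). Of 15213 genes tested, 842 were higher and 444 lower with chaetocin (limma, Benjamini-Hochberg adjusted p under 0.05), which is 8.45% of the genes. The larger changes were mostly increases: 327 genes were at least 2-fold higher and 80 at least 2-fold lower, and 75 and 4 passed 8-fold. A call with 3 libraries per group makes separation likely, and in all 1286 the 3 chaetocin libraries lay wholly above or below the 3 DMSO libraries. That held for 26.04% of all tested genes, where chance gives 10%. The median log2 fold change of all genes was -5e-04. The first principal component took 41.7% of the variance, with DMSO libraries at -38.21, -36.07 and -29.33 and chaetocin libraries at 33.03, 35.82 and 34.76. The number of higher genes was 550, 538 and 544 without chaetocin replicate 1, 2 and 3, and the number of lower genes 265 without DMSO replicate 2.

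**Figure D1:**
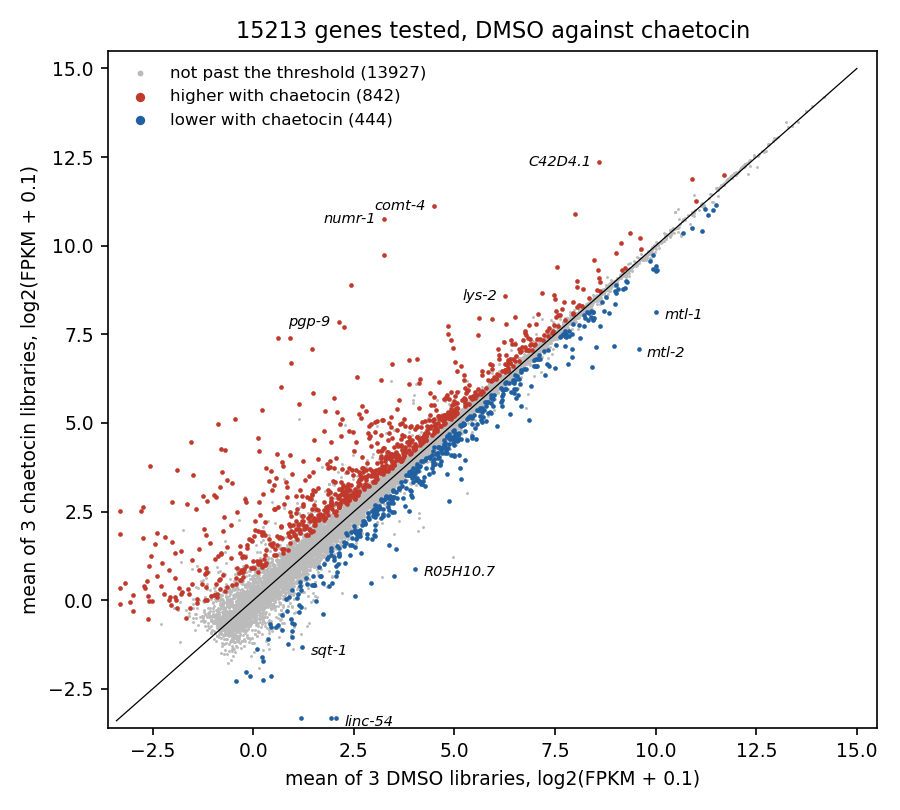
Mean level of each of the 15213 tested genes in the 3 DMSO libraries (x axis) and the 3 chaetocin libraries (y axis), both as log2(FPKM + 0.1), with the line of equal levels. Red points are the 842 genes higher and blue points the 444 genes lower with chaetocin.

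The largest increase on the log2(FPKM + 0.1) scale, which understates the change of genes with low values, was that of numr-1 (WBGene00017270, chromosome III, 7362619 to 7363464, WBcel235), a gene known for its induction by metals, with a log2 fold change of 8.49 ± 0.93 (limma, adjusted p = 0.001825). Its DMSO libraries stood at 2.90, 1.42 and 24.1 FPKM, and without DMSO replicate 3 the log2 fold change was 9.66, without DMSO replicate 2 7.66. The near-identical copy numr-2 rose to 848 ± 156 FPKM, and both copies were listed with equal FPKM in all 3 DMSO libraries, so their separate levels are uncertain. The neighbours comt-4 (chromosome V, 2049217 to 2050185) and comt-5 (2052226 to 2053609), named as catechol-O-methyltransferases, had log2 fold changes of 7.50 ± 0.85 and 7.35 ± 0.86, with comt-5 rising from 5.24 ± 6.76 to 478 ± 20.8 FPKM. The cytochrome P450 gene cyp-33C12 had a log2 fold change of 7.55 ± 0.84. Other genes among the 10 largest increases were oac-14, named as an acyltransferase (1.79 ± 1.34 to 167 ± 8.89 FPKM), clx-1 (0.446 ± 0.642 to 31.3 ± 1.75) and ZK742.3 (1.81 ± 1.003 to 103 ± 3.56). Y46H3D.8 was listed at 0, 0 and 0.204 FPKM in the DMSO and 15.7, 11.7 and 13.7 in the chaetocin libraries, and F13E9.8 at 0.171, 0 and 0.555 against 22.6, 22.6 and 20.97. Adjusted p of the 10 genes lay between 8.098e-05 (ZK742.3) and 0.003507 (numr-2) in the limma test. DMSO replicate 3 lay above the other DMSO libraries in several of them: without it the log2 fold changes of comt-4, comt-5, cyp-33C12, clx-1, numr-2 and F13E9.8 were 8.58, 8.44, 8.56, 7.48, 8.62 and 7.07. Without DMSO replicate 2 those of comt-4, comt-5, cyp-33C12, numr-2 and F13E9.8 were 6.78, 6.58, 6.69, 6.62 and 5.71.

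Decreases were smaller. Among the 10 largest, linc-54, a long noncoding RNA, stood at 3.04, 5.83 and 3.38 FPKM with DMSO, the small nuclear RNA gene T08G5.11 at 3.47, 3.81 and 3.86, and Y13C8A.1 at 1.04, 1.98 and 3.53. Each of these genes was listed at 0 in all 3 chaetocin libraries, so no fold is given (limma, adjusted p = 7.829e-05, 1.847e-05 and 0.001309). R05H10.7 fell from 16.17 ± 0.539 to 1.75 ± 0.905 FPKM, a log2 fold change of -3.30 ± 0.41 (limma, adjusted p = 0.003302). F35E8.10 fell from 11.2 ± 1.74 to 1.5004 ± 0.234 and the cuticle collagen gene sqt-1 from 2.23 ± 0.719 to 0.297 ± 0.165 FPKM. Y51H4A.5, E02H4.4 and the channel gene acd-1 had log2 fold changes of -2.43 ± 0.13, -2.42 ± 0.14 and -2.13 ± 0.26, with limma adjusted p of 6.193e-05, 0.0001006 and 0.003324.

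Genes of xenobiotic metabolism moved in both directions, with the larger changes upward. Of 55 cytochrome P450 genes tested, 20 rose and 8 fell (23 and 11 adjusted over the list alone). cyp-33C5 rose from 1.51 ± 0.362 to 64.2 ± 3.04 FPKM, cyp-33C7 from 5.86 ± 1.01 to 78.2 ± 3.61 and cyp-33C4 from 3.31 ± 0.343 to 27.5 ± 0.553, whereas cyp-34A9 fell from 38.6 ± 1.13 to 15.48 ± 0.191. Camera placed the family above other genes (adjusted p = 0.0008309; adjusted p = 0.2194 with an estimated correlation). That call was lost without chaetocin replicate 1, 2 or 3 (adjusted p = 0.1386, 0.1205 and 0.3247) and with a stricter filter (0.1039). Without those libraries the list's mean log2 fold change fell from 1.0178 to 0.6627, 0.6424 and 0.6362. The filter still asked for 3 libraries, so members above it only with chaetocin were not tested in those fits. Among 50 UDP-glucuronosyltransferases, which conjugate lipophilic compounds, 15 rose and 5 fell (17 and 14 adjusted over the list alone; camera, adjusted p = 0.1563). They included ugt-62 (10.8 ± 0.932 to 102 ± 6.22 FPKM), ugt-1 (3.94 ± 1.03 to 52.2 ± 0.865), ugt-2 (3.32 ± 0.775 to 40.5 ± 1.604) and ugt-61 (4.51 ± 0.470 to 34.2 ± 0.628). Of 43 glutathione S-transferases, 11 rose and 9 fell (14 and 10 adjusted over the list alone; camera, adjusted p = 0.1879). gst-33 rose from 2.66 ± 1.66 to 136 ± 7.39 FPKM, gst-5 from 30.04 ± 0.687 to 162 ± 16.9 and gst-9 from 0.538 ± 0.270 to 10.3 ± 0.702, and gst-27 fell from 51.3 ± 0.151 to 32.5 ± 1.11.

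ABC exporters rose in 9 of 32 cases with 0 lower (9 adjusted over the list alone; camera, adjusted p = 8.959e-05; adjusted p = 0.4493 with an estimated correlation). The P-glycoprotein gene pgp-9 went from 4.24 ± 2.18 to 232 ± 4.72 FPKM, 54.7-fold, and mrp-3 from 4.39 ± 0.222 to 31.5 ± 1.14, while pgp-14 and pgp-5 rose 5.37-fold and 4.21-fold. Among 175 nuclear hormone receptors 15 rose and 3 fell (16 and 5 adjusted over the list alone; camera, adjusted p = 0.2732). nhr-106 rose from 2.94 ± 0.0569 to 15.7 ± 0.441 FPKM, and nhr-142, nhr-184 and nhr-130 rose with log2 fold changes of 2.79 ± 0.21, 1.42 ± 0.11 and 1.005 ± 0.08.

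Of 19 targets of SKN-1, the oxidative stress regulator, 4 rose and 4 fell (6 and 4 adjusted over the list alone; camera, adjusted p = 0.345; fry, higher, adjusted p = 0.02698). Besides gst-5, skr-5 rose from 3.997 ± 0.363 to 9.98 ± 0.380 FPKM and gst-6 from 7.03 ± 1.47 to 14.4 ± 0.864, and nit-1, a nitrilase gene, fell from 7.98 ± 0.259 to 3.82 ± 0.187. The reporter gene gst-4 stood at 2.496 ± 0.0455 and 3.29 ± 0.215 FPKM with DMSO and chaetocin, a log2 fold change of 0.38 ± 0.11 that missed the threshold (limma, adjusted p = 0.08594). The glutamate-cysteine ligase gene gcs-1 had 56.9 ± 3.56 and 57.3 ± 1.05 FPKM (limma, adjusted p = 0.935), and its log2 fold change of 0.01 was -0.005 on unscaled FPKM. Neither skn-1 (log2 fold change -0.07, adjusted p = 0.5325) nor its repressor wdr-23 (0.13, adjusted p = 0.09948) passed the limma test. Of 22 thiol redox genes, gpx-1, a glutathione peroxidase gene, was the 1 that rose, from 28.7 ± 3.18 to 184 ± 10.8 FPKM (1 adjusted over the list alone; camera, adjusted p = 0.5412). Thioredoxin reductase trxr-1 had 96.8 ± 4.83 and 98.3 ± 1.297 FPKM (limma, adjusted p = 0.8198), and gpx-6, gpx-5 and glrx-3 had limma adjusted p of 0.1181, 0.2574 and 0.2996. trx-1 was below the filter, at 0.53, 0.43 and 0.23 FPKM with DMSO and 0.6, 0.14 and 0.17 with chaetocin.

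Metal response genes split. Of 18 tested, 8 rose and 3 fell (8 and 3 adjusted over the list alone; camera, adjusted p = 0.01842; adjusted p = 0.5197 with an estimated correlation). Besides numr-1 and numr-2, cdr-4, a cadmium-responsive gene, rose from 5.07 ± 0.613 to 27.4 ± 1.32 FPKM and the ferritin gene ftn-1 from 10.5 ± 0.213 to 35.7 ± 0.652. The metallothionein genes mtl-1 and mtl-2 had log2 fold changes of -1.86 ± 0.05 and -2.51 ± 0.08 (limma, adjusted p = 6.548e-06 and 8.722e-06). The list call was lost without chaetocin replicate 1, 2 or 3 (adjusted p = 0.2223, 0.2154 and 0.3146) and with a stricter filter (0.07022). Without those libraries the list's mean log2 fold change fell from 1.2743 to 0.9426, 0.9048 and 0.9262. Members above the filter only with chaetocin were not tested in those fits. Of 17 targets of DAF-16, the transcription factor of insulin signalling, 2 rose and 9 fell (2 and 12 adjusted over the list alone; camera, adjusted p = 1.815e-07; adjusted p = 0.1648 with an estimated correlation). dod-3 fell from 495 ± 11.4 to 145 ± 12.1 and the lysozyme gene lys-7 from 242 ± 10.8 to 136 ± 5.38 FPKM. The superoxide dismutase gene sod-3 had 2.03 ± 0.348 and 1.334 ± 0.163 FPKM (limma, adjusted p = 0.1381).

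Among heat shock genes, hsp-16.2 went from 2.36 ± 1.234 to 10.4 ± 1.49 FPKM (log2 fold change 2.26 ± 0.43; limma, adjusted p = 0.02147), hsp-16.11 from 7.97 ± 3.30 to 26.9 ± 3.33, hsp-16.41 from 2.001 ± 0.850 to 7.52 ± 1.16 and hsp-17 from 12.95 ± 1.15 to 31.97 ± 2.39. The hsp-16 genes come in near-identical pairs, so the level of each copy is uncertain. hsp-70 rose from 0.347 ± 0.0875 to 0.898 ± 0.0378 FPKM. In all, 6 of 19 heat shock response genes rose and 0 fell (8 adjusted over the list alone; camera, adjusted p = 3.034e-05; adjusted p = 0.1648 with an estimated correlation). Leaving out 1 library ended some calls: hsp-16.2 without chaetocin replicate 1, chaetocin replicate 2 or chaetocin replicate 3 (adjusted p up to 0.08), hsp-70 without DMSO replicate 1 or DMSO replicate 2 (up to 0.0868), hsp-16.41 without chaetocin replicate 1 or chaetocin replicate 3 (up to 0.0597) and hsp-16.11 without chaetocin replicate 2 (0.05437). hsp-70 had no fit without a chaetocin library, since its DMSO values lay below the filter. The regulator hsf-1 had 45.8 ± 1.92 and 42.8 ± 1.27 FPKM (limma, adjusted p = 0.3039).

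In the endoplasmic reticulum unfolded protein response, 1 of 24 genes rose (0 adjusted over the list alone; camera, adjusted p = 0.3006), the regulator xbp-1, with 175 ± 4.29 and 193 ± 3.03 FPKM. The xbp-1 call was lost on unscaled FPKM (adjusted p = 0.1306), with no filter (0.05117), with a stricter filter (0.05323) and without DMSO replicate 1, DMSO replicate 2, chaetocin replicate 1, chaetocin replicate 2 or chaetocin replicate 3 (up to 0.1451). hsp-4, crt-1, dnj-20 and pek-1 had limma adjusted p of 0.8236, 0.07958, 0.1363 and 0.1938, with hsp-4 at 131 ± 9.88 and 134 ± 2.36 FPKM. Of 12 mitochondrial unfolded protein response genes 0 passed the limma test (4 at unadjusted p under 0.05; camera, adjusted p = 0.6778), and hsp-6 had 306 ± 17.2 and 303 ± 3.87 FPKM (limma, adjusted p = 0.9135).

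**Figure D2:**
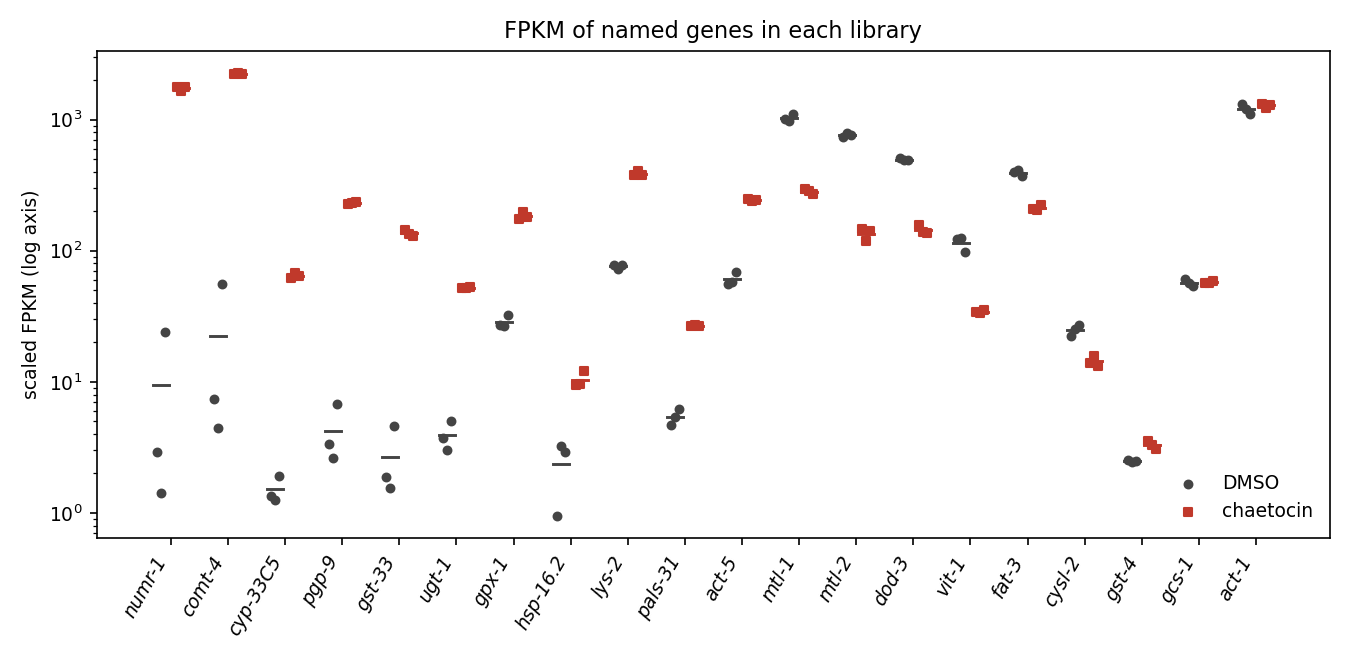
Scaled FPKM on a log axis of 20 genes in each of the 3 DMSO libraries (dark circles) and 3 chaetocin libraries (red squares), with bars at the group means. The means of numr-1 were 9.48 FPKM with DMSO and 1728 with chaetocin, and those of mtl-2 766.439 and 134.909.

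Of 14 genes of the hydrogen sulphide and hypoxia response, 5 fell and 0 rose (6 adjusted over the list alone; camera, adjusted p = 0.001212; adjusted p = 0.255 with an estimated correlation). The cysteine synthase family gene cysl-2 fell from 24.8 ± 2.53 to 14.3 ± 1.27 FPKM (log2 fold change -0.79 ± 0.10; limma, adjusted p = 0.003086). cysl-3, the HIF-1 target nhr-57 and rhy-1 had log2 fold changes of -0.37 ± 0.05, -0.59 ± 0.08 and -0.55 ± 0.10. The list call was lost with a stricter filter (adjusted p = 0.1397), and the rhy-1 call without DMSO replicate 2, DMSO replicate 3, chaetocin replicate 2 or chaetocin replicate 3 (up to 0.085). Of 8 osmotic response genes the 1 that fell was hmit-1.1, an inositol transporter gene (2.87 ± 0.118 to 0.884 ± 0.0761 FPKM; 1 adjusted over the list alone; camera, adjusted p = 0.3122). gpdh-1, nlp-29 and T22B7.3 had limma adjusted p of 0.5495, 0.4381 and 0.319.

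The list for the intracellular pathogen response, a response to microsporidia and viruses, took every gene named pals and some others. The pals genes were thus chosen by name and not by their induction. Of 29 genes tested 18 rose and 0 fell (23 higher adjusted over the list alone). Camera gave an adjusted p of 2.964e-14, and of 0.1648 with an estimated correlation. The pals genes made up 22 of those tested and 13 of those that rose. pals-31 rose from 5.42 ± 0.799 to 26.8 ± 0.341 FPKM, and pals-23 and pals-24 rose 2.28-fold and 2.21-fold, beside skr-5. pals-5, a common reporter of the response, was at 0.191, 0.0704 and 1.55 FPKM in the DMSO and 0.557, 0.368 and 0.758 in the chaetocin libraries, and its log2 fold change of 0.56 ± 0.82 did not pass (limma, adjusted p = 0.7629). The mean FPKM of pals-5 pointed the other way (0.603 with DMSO and 0.561 with chaetocin). Without DMSO replicate 2 the sign of its log2 fold change turned (-0.11). Readouts of PMK-1, the p38 kinase of intestinal immunity, rose in 7 of 13 cases with 0 lower (9 and 1 adjusted over the list alone; camera, adjusted p = 4.191e-06; adjusted p = 0.2071 with an estimated correlation). The lysozyme gene lys-2 rose from 76.1 ± 3.11 to 386 ± 14.8 FPKM, lys-8 from 191 ± 6.10 to 266 ± 1.54, hpo-6 from 3.64 ± 0.482 to 14.97 ± 0.498 and the lectin gene clec-67 from 1.27 ± 0.413 to 8.45 ± 0.456. Genes that respond to blocked translation rose in 3 of 8 cases (5 adjusted over the list alone; camera, adjusted p = 0.0008309; adjusted p = 0.2071 with an estimated correlation). These were pgp-5, ZK6.11 (5.55 ± 1.19 to 18.5 ± 2.32 FPKM) and irg-1 (0.687 ± 0.211 to 1.604 ± 0.220), while cebp-1 did not pass (limma, adjusted p = 0.06694). The irg-1 call was lost with no filter (adjusted p = 0.05119) and without DMSO replicate 2, DMSO replicate 3, chaetocin replicate 1, chaetocin replicate 2 or chaetocin replicate 3 (up to 0.1212).

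Effector families of immunity went both ways. Among 99 C-type lectins 23 rose and 13 fell (27 and 16 adjusted over the list alone; camera, adjusted p = 0.0786). clec-83 rose from 89.97 ± 4.47 to 254 ± 5.802 FPKM, clec-186 from 9.29 ± 0.868 to 33.8 ± 1.44 and clec-227 from 2.25 ± 0.308 to 14.98 ± 0.463, and clec-218 fell from 35.6 ± 1.94 to 10.6 ± 0.663. Of 13 lysozymes 5 rose and 4 fell (6 and 4 adjusted over the list alone; camera, adjusted p = 0.345), with lys-1 at 177 ± 2.22 and 389 ± 3.47 FPKM and ilys-5 at 1049 ± 17.1 and 640.3 ± 23.1. Of 36 antimicrobial peptide genes 3 rose and 4 fell (5 and 8 adjusted over the list alone). spp-1 rose 1.66-fold, and spp-8, spp-14 and spp-4 fell with log2 fold changes of -1.15 ± 0.05, -0.73 ± 0.05 and -0.71 ± 0.09. The list's median of 0.03 and mean of 0.12 were above 0 where camera pointed down (adjusted p = 0.9998).

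Of 15 genes of fatty acid desaturation and elongation, 2 rose and 6 fell (3 and 9 adjusted over the list alone; camera, adjusted p = 0.001212; adjusted p = 0.6245 with an estimated correlation). The desaturase genes fat-3 and fat-6 fell from 393 ± 21.9 to 212 ± 9.01 and from 299 ± 8.08 to 215 ± 9.65 FPKM, the elongase gene elo-2 fell by 0.55 on the log2 scale, and elo-6 rose by 0.28. Among 15 fasting response genes 2 rose and 4 fell (3 and 5 adjusted over the list alone; camera, adjusted p = 0.1669). The lipase genes lipl-5, lipl-2 and lipl-3 had log2 fold changes of -0.74 ± 0.03, -1.103 ± 0.05 and -0.54 ± 0.05, and hacd-1 rose 1.73-fold. In one-carbon metabolism 1 of 15 genes rose and 4 fell (1 and 5 adjusted over the list alone; camera, adjusted p = 0.08452). The S-adenosylmethionine synthetase gene sams-1 fell from 72.9 ± 1.56 to 53.8 ± 1.98 FPKM, pmt-2 from 215 ± 4.74 to 174 ± 3.73 and cth-1 from 10.6 ± 0.201 to 7.102 ± 0.677, and cth-2 rose from 76.8 ± 0.617 to 90.4 ± 3.62.

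Of 6 vitellogenins, the yolk protein genes of the adult intestine, 1 rose and 2 fell (1 and 5 adjusted over the list alone; camera, adjusted p = 0.007423; adjusted p = 0.6245 with an estimated correlation). vit-1 fell from 115 ± 14.7 to 34.1 ± 0.902 FPKM and vit-5 from 2515 ± 310.3 to 1854 ± 54.5, vit-4 rose from 248 ± 33.5 to 343 ± 14.9, and vit-2 had 5855 ± 664 and 4751 ± 169 FPKM (limma, adjusted p = 0.09622, and 0.008994 without DMSO replicate 3). The vit-5 call was lost without DMSO replicate 1, DMSO replicate 2, chaetocin replicate 1, chaetocin replicate 2 or chaetocin replicate 3 (adjusted p up to 0.1048), and the vit-4 call with no filter (0.05107) and without DMSO replicate 2, chaetocin replicate 1, chaetocin replicate 2 or chaetocin replicate 3 (up to 0.09881).

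The major sperm protein list held 43 tested genes, 28 of them named msp and the others named nspd, nspe, ssq or sss. The msp genes are near-identical copies. Of the 43 genes, 0 passed the limma test (16 at unadjusted p under 0.05), while 41 had a log2 fold change above 0. Their median was 0.18 (camera, adjusted p = 4.191e-06, and 0.6245 with an estimated correlation). Of 14 spermatogenesis genes the 1 that rose was try-5, a seminal fluid protease gene (0.340 ± 0.0776 to 1.80 ± 0.482 FPKM; 1 adjusted over the list alone; camera, adjusted p = 0.03877; adjusted p = 0.639 with an estimated correlation). peel-1, gsp-3 and spe-41 had limma adjusted p of 0.1316, 0.1551 and 0.2375, and gsp-3 passed without chaetocin replicate 2 (adjusted p = 0.0157) and with the replicate block by title number (0.04619). The spermatogenesis call was lost with a stricter filter (adjusted p = 0.3755) and without DMSO replicate 1, DMSO replicate 2, chaetocin replicate 1 or chaetocin replicate 3 (up to 0.2951). All 20 oocyte and early embryo genes had log2 fold changes below 0, with a median of -0.07, and 0 passed the limma test (3 at unadjusted p under 0.05; camera, adjusted p = 0.001039; adjusted p = 0.639 with an estimated correlation). Of 20 germline stem and meiotic genes 0 passed the limma test (3 at unadjusted p under 0.05; camera, adjusted p = 0.418).

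Among 99 collagens 1 rose and 9 fell (1 and 10 adjusted over the list alone; camera, adjusted p = 0.03797; adjusted p = 0.7813 with an estimated correlation), with a median of -0.09 and a mean of -0.02. That call was lost on unscaled FPKM (adjusted p = 0.09871), with no filter (0.3019), with the replicate block by title number (0.2286) and without DMSO replicate 1, DMSO replicate 3, chaetocin replicate 2 or chaetocin replicate 3 (up to 0.6111). The mean turned to 0.0539 with no filter, 0.0704 without DMSO replicate 1 and 0.1871 without chaetocin replicate 3, and was -0.1154 without DMSO replicate 3. col-143 fell from 349 ± 11.4 to 246 ± 23.3 FPKM, col-80 from 599 ± 35.3 to 444 ± 46.6 and col-135 from 91.2 ± 5.36 to 74.7 ± 0.813, and col-151 rose 3.14-fold. The col-80 call was lost without DMSO replicate 2, DMSO replicate 3, chaetocin replicate 2 or chaetocin replicate 3 (adjusted p up to 0.07486), and the col-135 call without DMSO replicate 2, chaetocin replicate 1 or chaetocin replicate 3 (up to 0.05511). Of 23 molting and larval cuticle genes, sqt-1 and the period homologue lin-42 were the 2 that fell (2 adjusted over the list alone; camera, adjusted p = 0.007439; adjusted p = 0.6245 with an estimated correlation). The molting call was lost with a stricter filter (adjusted p = 0.3648), with the replicate block by title number (0.1229) and without DMSO replicate 1 or DMSO replicate 3 (up to 0.1827). lin-42 had 5.78 ± 0.779 and 3.20 ± 0.752 FPKM, and its call was lost with no filter (0.0556) and without DMSO replicate 1, DMSO replicate 2, chaetocin replicate 2 or chaetocin replicate 3 (up to 0.124). rol-6 and mlt-10 did not pass (limma, adjusted p = 0.08539 and 0.1014), but rol-6 passed with the replicate block (adjusted p = 0.03685) and without chaetocin replicate 1 (0.03037), and mlt-10 without DMSO replicate 3 (0.04633).

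Of 12 intestine markers 5 rose and 4 fell (5 and 4 adjusted over the list alone; camera, adjusted p = 0.7303). The intestinal actin gene act-5 rose from 60.7 ± 6.65 to 244 ± 4.19 FPKM (log2 fold change 2.01 ± 0.07; limma, adjusted p = 1.361e-05) and the intermediate filament gene ifb-2 rose 1.27-fold, whereas mtl-2 and the cysteine protease gene cpr-6 fell (cpr-6 from 620.3 ± 8.25 to 503 ± 6.68). The limma test called 0 of 11 pharynx, 0 of 15 body wall muscle and 0 of 18 neuron markers (3, 0 and 1 at unadjusted p under 0.05; camera, adjusted p = 0.0786, 0.418 and 0.8198). The reference genes act-1, cdc-42 and pmp-3 had log2 fold changes of 0.09, -0.02 and -0.01 (limma, adjusted p = 0.4933, 0.8896 and 0.9239).

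**Figure D3:**
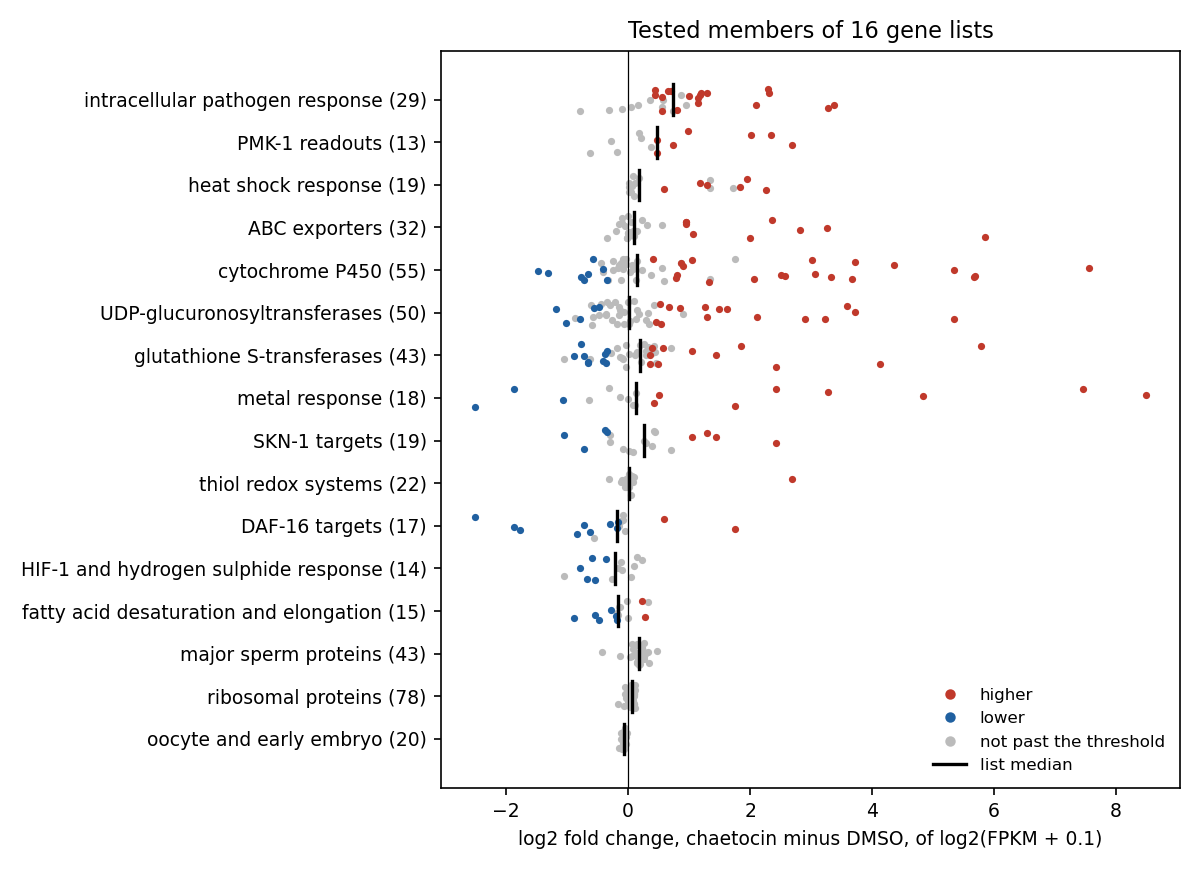
Log2 fold changes (chaetocin minus DMSO) of the tested members of 16 gene lists, 1 point per gene, with list sizes in parentheses, red for higher, blue for lower, grey for genes not past the threshold and a black bar at the list median. The points of cytochrome P450 (20 higher, 8 lower) spread widely, and those of 78 ribosomal proteins lie close to 0.

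Of 78 ribosomal protein genes 0 passed the limma test (4 at unadjusted p under 0.05), while 70 had log2 fold changes above 0 with a median of 0.06 (camera, adjusted p = 0.0007868; adjusted p = 0.7813 with an estimated correlation). That call was lost without DMSO replicate 1 or chaetocin replicate 1 (adjusted p up to 0.1386) and with the replicate block by title number (0.2005). Of 33 proteasome genes the 1 past the threshold was rpt-6 (160.4 ± 1.46 to 175 ± 1.096 FPKM; 0 adjusted over the list alone), and 31 had log2 fold changes above 0 (camera, adjusted p = 0.001039; adjusted p = 0.6245 with an estimated correlation; lost without chaetocin replicate 2, 0.09214, and with the block by title number, 0.1113). The rpt-6 call was lost on unscaled FPKM (adjusted p = 0.07395) and without DMSO replicate 1, DMSO replicate 2, chaetocin replicate 1, chaetocin replicate 2 or chaetocin replicate 3 (up to 0.1412). pas-3, pas-5 and pbs-5 had limma adjusted p of 0.1103, 0.1207 and 0.1443. Of 10 mitochondrially encoded genes 2 fell, the cytochrome c oxidase genes ctc-3 (2908 ± 149 to 2271 ± 97.2 FPKM) and ctc-2 (2378 ± 90.7 to 2092 ± 72.7) (2 adjusted over the list alone; camera, adjusted p = 0.03673; adjusted p = 0.6743 with an estimated correlation). ctc-1 and nduo-6 had limma adjusted p of 0.1501 and 0.4156, and nduo-6 passed without chaetocin replicate 3 (adjusted p = 0.01499). The mitochondrial list was lost without DMSO replicate 1, DMSO replicate 2, chaetocin replicate 1 or chaetocin replicate 2 (adjusted p up to 0.2001). ctc-2 was lost without the same libraries (up to 0.1686), with no filter (0.08068) and with pseudocounts of 0.5 and 1 (0.05017 and 0.05139). Limma called 0 of 32 genes of nuclear-encoded oxidative phosphorylation and 0 of 15 of ribosome biogenesis (2 and 4 at unadjusted p under 0.05; camera, adjusted p = 0.315 and 0.418).

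Of 25 lysine methyltransferases and H3K9 readers the 1 that fell was set-26, with 30.96 ± 0.830 and 27.04 ± 0.639 FPKM (0 adjusted over the list alone), and 18 had log2 fold changes below 0 (camera, adjusted p = 0.01842; adjusted p = 0.6245 with an estimated correlation). The list call was lost without DMSO replicate 2 or chaetocin replicate 1 (adjusted p up to 0.1268) and the set-26 call without DMSO replicate 1, DMSO replicate 2, chaetocin replicate 1, chaetocin replicate 2 or chaetocin replicate 3 (up to 0.1352). The H3K9 methyltransferase genes met-2 and set-25 had 36.7 ± 2.02 and 33.7 ± 0.803, and 5.16 ± 0.207 and 4.91 ± 0.757 FPKM (limma, adjusted p = 0.2337 and 0.784), and lin-65 and mes-3 had limma adjusted p of 0.06107 and 0.1634. Of 64 histone genes, many of them near-identical, limma called 0 (5 at unadjusted p under 0.05; camera, adjusted p = 0.1825), and of 18 DNA damage and apoptosis genes 0 (0 at unadjusted p under 0.05; camera, adjusted p = 0.4418). Of 29 argonautes and small RNA factors 2 rose, sago-2 from 2.21 ± 0.214 to 4.63 ± 0.466 and ppw-1 from 75.8 ± 2.93 to 90.2 ± 1.89 FPKM (2 adjusted over the list alone; camera, adjusted p = 0.8654). The list's median was -0.03 and its mean 0.03, with camera pointing down and fry up, and mut-14 and C04F12.1 had limma adjusted p of 0.1456 and 0.2135. Of 28 autophagy genes 2 rose, epg-3 (37.4 ± 3.03 to 73.99 ± 2.58 FPKM) and the cargo receptor gene sqst-1 (43.8 ± 1.94 to 53.8 ± 0.382) (2 adjusted over the list alone; camera, adjusted p = 0.9267). Their list had a median of -5e-04 and a mean of 0.03 with camera pointing up, and atg-4.1 and lgg-2 had limma adjusted p of 0.1137 and 0.1789.

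Over all 44 lists, camera called 20, with 11 higher and 9 lower, and fry called 19, of which 11 were called by both. The 9 called by camera but not by fry were major sperm proteins (fry, adjusted p = 0.1685), ribosomal proteins (0.3959), oocyte and early embryo (0.2511), proteasome (0.0662), molting and larval cuticle (0.1793), lysine methyltransferases and H3K9 readers (0.1032), mitochondrially encoded genes (0.3688), collagens (0.5849) and spermatogenesis (0.1261). The 8 called by fry but not by camera were, higher, UDP-glucuronosyltransferases (0.0001414), lysozymes (0.0003436), C-type lectins (0.0009462), nuclear hormone receptors (0.003447), glutathione S-transferases (0.01111) and SKN-1 targets (0.02698), and, lower, fasting response (0.01077) and osmotic response (0.03089). Some lists not called by camera were called under other settings. With the stricter filter these were C-type lectins (adjusted p = 0.001162), UDP-glucuronosyltransferases (0.000112) and glutathione S-transferases (0.0467), all higher, and pharynx markers, lower (0.03805). With no filter they were C-type lectins (0.01414) and glutathione S-transferases (0.03943), on unscaled FPKM C-type lectins (0.04406) and with the replicate block pharynx markers (0.0153). With the block by title number they were C-type lectins, higher (0.02681), and histones (0.002165), germline stem and meiotic genes (0.02584) and one-carbon metabolism (0.04362), lower. Without DMSO replicate 3 they were C-type lectins (0.03264) and UDP-glucuronosyltransferases (0.04715), higher, and one-carbon metabolism (0.02018), germline stem and meiotic genes (0.02593) and argonautes (0.03132), lower. Pharynx markers were called lower without DMSO replicate 1 (0.0003229) and chaetocin replicate 3 (0.04221), and histones without chaetocin replicate 2 (0.0003902). With an estimated correlation camera called 0 lists (7 at unadjusted p under 0.05). Camera with the preset correlation also called up to 18 lists in other splits of the same 6 libraries, so a list call alone is weak evidence beside the counts of members.

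The replicate block ended the calls of 11 named genes and of 0 lists: irg-1 (adjusted p = 0.0535), ppw-1 (0.05903), vit-5 (0.08098), col-80 (0.08196), vit-4 (0.08909), hsp-70 (0.09003), rhy-1 (0.09407), xbp-1 (0.1137), rpt-6 (0.1409), set-26 (0.1479) and ctc-2 (0.155). The block by title number ended 26 calls, those of the lists proteasome (adjusted p = 0.1113), molting and larval cuticle (0.1229), ribosomal proteins (0.2005) and collagens (0.2286) and those of the genes sago-2 (adjusted p = 0.05206), spp-4 (0.05236), vit-4 (0.05248), col-143 (0.0562), elo-6 (0.06753), ppw-1 (0.06908), sqst-1 (0.07578), cth-2 (0.07588), lin-42 (0.08237), col-151 (0.09416), col-135 (0.09592), cth-1 (0.1025), ctc-3 (0.1063), nhr-57 (0.1157), hsp-70 (0.1209), irg-1 (0.1328), xbp-1 (0.1517), col-80 (0.18), set-26 (0.1804), rpt-6 (0.209), rhy-1 (0.2122) and ctc-2 (0.2641). Neither number was shown to pair the libraries. DMSO replicate 3 and chaetocin replicate 2 shared no title number with a library of the other group. In the block by title number they therefore added nothing to the group difference, so calls lost there partly reflect fewer libraries.

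At the transcript level, 657 of 21002 transcripts were higher and 323 lower with chaetocin (limma, adjusted p under 0.05). They belonged to 934 genes, of which 841 were also called at the gene level. Without chaetocin replicate 1, 2 or 3 there were 346, 324 and 359 transcripts higher and 191, 161 and 194 lower, and without DMSO replicate 1 or 2 there were 176 and 146 lower.

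The authors' deposited table called 1456 of its 16062 coding genes at the same threshold, 895 higher and 561 lower with chaetocin. Of the 14336 genes tested in both, 1399 were called in the authors' deposited table and 1242 here, and 1108 were called in both, all with the same sign. Independent lists of these sizes would share 48.828 higher and 16.099 lower genes, and 738 and 370 were shared with the authors' deposited table. Its log2 fold changes correlated with those computed here at r = 0.9834 across genes, which are not independent replicates, and both sources rest on the same 6 libraries. Of the genes tested in both, 291 were called only in the authors' deposited table and 134 only here. Among named genes called here, sqt-1, set-26 and rpt-6 were not called by the authors (deposited p = 0.2168, 0.1339 and 0.2194). The named coding genes numr-1, comt-4, comt-5, cyp-33C12 and Y13C8A.1 had no value there, so their calls could not be compared. The authors called mlt-10, ctc-1, lin-65, vit-2 and pek-1, which did not pass here (deposited p = 0.0005888, 0.002647, 0.006868, 0.04161 and 0.04943).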

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

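Pseudocounts of 0.01, 0.5 and 1 and robust variance moderation were tried after seeing the data, and the planned count-based alternative was not run because the tables hold FPKM. Across 2 other scalings, 2 other filters, these pseudocounts and robust moderation, the numbers of called genes, transcripts and lists stayed within 1.5 times the reported ones. With the genes of the authors' deposited table alone, an alternative run for gene counts only, 873 genes were higher and 472 lower. Calls shared with the reported 1286 were 1272 of 1294 with median-of-ratios scaling, 1194 of 1235 unscaled, 1113 of 1177 with no filter and 906 of 951 with the stricter filter, which tests fewer genes and gave a value to 141 of the 173 named genes and lists. A fold threshold of 2 left 327 genes higher and 80 lower by construction, and camera with an estimated correlation called 0 lists (7 at unadjusted p under 0.05) where fry called 19. The replicate numbers were not shown to pair the libraries. Deviations of same-numbered libraries correlated at 0.106, 0.067 and -0.026, and those of differently numbered libraries at -0.15 to 0.078. Chaetocin replicate 2 correlated best with DMSO replicate 3 (0.078). These values neither show nor exclude a shared culture or day. With the replicate block, 582 genes were higher and 255 lower, 336 transcripts higher and 112 lower, and 21 lists were called. With a replicate block by the number in the sample titles these were 524, 205, 94, 23 and 20, and the log2 fold changes of trxr-1, hsp-4 and gcs-1, not called in either fit, turned to -0.021, -0.0431 and -0.0221. DMSO replicate 3 and chaetocin replicate 2 stood alone in their title-number blocks and added nothing to that group difference. Leaving out 1 library gave 538 to 852 genes higher, 265 to 504 lower, 324 to 629 transcripts higher, 146 to 259 lower and 14 to 23 lists. Without DMSO replicate 3, 1356 genes were called, 1060 of them also with it. Of 111 named called genes, 89 kept their call with each of the 6 libraries left out, and 7 kept it in the 3 such fits in which they passed the filter. Of 20 called lists, 11 kept their call with each library left out, and no called gene changed sign under any setting. Uncalled genes whose sign turned had log2 fold changes of -0.1102 to 0.7838 (pals-5), -0.063 to 0.0162 (cdc-42), -0.0589 to 0.019 (hsp-6), -0.0579 to 0.016 (pmp-3), -0.0171 to 0.0452 (trxr-1), -0.0296 to 0.0784 (hsp-4), -0.0343 to 0.0471 (gcs-1) and -0.1811 to 0.048 (set-25) with 1 library left out, and gcs-1 was at -0.005 unscaled. Fewer libraries lower the power by construction. The filter still asked for 3 libraries. Genes above it in only 1 group thus left the test when a library of that group was dropped. Calls lost in such fits therefore need not mean that libraries disagree. For the other changes the cause was not tested. Unknown depth leaves the precision of low genes unmeasured beyond the spread of 3 libraries.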

Other observations

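The family tests and the genes named here, the splits for genes and transcript usage, and the tests on DMSO replicate 3 and on neighbouring genes were chosen after the results were seen. Of 12 aspartyl protease genes (asp), 9 rose and 1, asp-13, fell (1-sided Fisher's exact test, Benjamini-Hochberg over 354 tests, adjusted p = 1.04e-07 for the rises), with asp-5 going from 662 ± 13.8 to 1315 ± 38.1 and asp-6 from 1911 ± 74.7 to 3772 ± 95.5 FPKM. Of 8 cysteine protease genes (cpr), 5 fell and 2 rose (adjusted p = 4.82e-05 and 0.639), with decreases of cpr-5 from 240.1 ± 10.9 to 116 ± 4.41 and cpr-1 from 1928 ± 60.3 to 1462 ± 57.7 FPKM and increases of cpr-4 from 255 ± 12.28 to 1892 ± 24.7 and cpr-3 from 5.34 ± 0.118 to 12.76 ± 0.878 FPKM. Of 12 galectin genes (lec), 6 rose and 1, lec-2, fell (adjusted p = 0.00063 for the rises), with lec-10 going from 77.8 ± 5.34 to 219.7 ± 3.10 and lec-6 from 778 ± 30.7 to 1189 ± 44.8 FPKM. Of the families named math and fbxa (F-box genes), 10 of 20 and 14 of 104 genes rose, and 1 of the latter, fbxa-72, fell (adjusted p = 2.02e-06 and 0.0294 for the rises), with math-37 at 2.80 ± 0.368 and 8.33 ± 0.844 and fbxa-74 at 3.89 ± 0.295 and 13.2 ± 1.01 FPKM. Related families did not pass: of the MATH domain family bath 0 of 32, and of the F-box families fbxb and fbxc 0 of 66 and 3 of 33 genes rose (adjusted p = 1, 1 and 1). In all, 23 of the 354 tests passed, several of them for families already fixed as lists. These tests treat genes as independent, though members of 1 family may share fragments or regulation. Their p-values do not measure the spread between libraries. C42D4.1 rose from 387 ± 71.95 to 5237 ± 39.5 FPKM.

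By gene type, 820 coding genes were higher and 434 lower of 14448 tested, against 12 and 6 of 481 pseudogenes and 6 and 2 of 149 noncoding RNA genes. On chromosome V 9.56% of the tested coding genes rose, and on chromosome I 3.24%.

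DMSO replicate 3 lay above the other DMSO libraries at the most induced genes, such as numr-1 (2.90, 1.42 and 24.1 FPKM) and comt-4 (7.42, 4.44 and 55.3). Its excess over DMSO replicate 2 was taken over 34 called genes more than 16-fold higher with chaetocin, chosen on DMSO replicate 1. The excess had a median of 2.14% of the chaetocin level (bootstrap interval over genes 1.82 to 2.6) and was positive in 88.2% of them. Such intervals do not measure the spread between libraries. With the roles of DMSO replicates 1 and 2 exchanged the median was 1.72% (quartiles 1.24 to 2.69) and 91.2% were positive. Genes 2- to 4-fold higher gave 5.29% (interval 2.41 to 6.97), which overlaps. Genes at least 2-fold lower gave 5.6% (interval 1.91 to 14.77), and 4.87% (-3.34 to 9.82) with the roles exchanged. Thresholds for this test were set after an earlier look at a similar set of genes, and a share positive in 90% of the genes within a factor of 2 was not met, nor was its opposite. A share of chaetocin RNA or reads in that library and a slight exposure of that culture therefore both stay open as candidate explanations, and cannot be told apart here.

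Neighbours were taken among the tested coding genes, so untested genes lying between them were skipped. In this order, genes higher with chaetocin lay next to each other more often than when calls were shuffled. There were 155 adjacent pairs, against a mean of 46.5 and a highest of 68 in 1000 permutations. Shuffling within chromosomes gave at most 79, which argues against unequal chromosomes as the whole cause. Same-strand pairs numbered 105 (mean 24.4, highest 40), divergent pairs 31 (mean 11.1, highest 21) and convergent pairs 19 (mean 11, highest 22), and read-through along 1 strand is argued against for the divergent pairs by their excess, and as the whole cause of the same-strand excess by the upstream gene gaining more FPKM in 57.1% of those pairs (95% interval 47.1 to 66.8), where 88.4% would be needed. Pairs of 1 family name numbered 42 (mean 1.9, highest 10), pairs with different family names 16 (mean 13, highest 25) and all pairs not of 1 family name 113 (mean 44.6, highest 67), but many genes of the last class carry no family name, so copies among them are unknown. Reads shared between gene copies and shared regulation of neighbouring genes both stay open and cannot be told apart here, and the rule for reading the 16 was settled after that count and the 113 were seen. Examples are 6 higher genes in a row among the tested genes from cyp-13A2 on chromosome II (9783384 to 9807569). Another is 7 from K08D8.5 on chromosome IV (12910647 to 12969289).

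Transcript usage differed in 78 of 3689 genes with all transcripts and in 57 of 2824 genes with transcripts above the filter in all 6 libraries, of which 42 were called in both. Other splits of the libraries, which mix both treatments within a group, gave up to 36 genes with all transcripts and up to 8 with those in all libraries. The second test holds no transcript listed at 0 by construction. It shows that 42 of the 78 were also called without such transcripts, and cannot tell how many others rest on them. With all transcripts, most of the genes with the smallest adjusted p had a transcript at 0 with DMSO. These were eef-2 (0 to 107.88 FPKM), C49H3.12 (0 to 20.77), F11A10.6, Y61A9LA.3, C35B1.2 and atn-1, while hpo-34 and unc-52 had none. erm-1, which encodes a membrane-cytoskeleton linker, moved its b.1 transcript from 18.86 ± 0.74 to 32.77 ± 2.35% of the gene's FPKM (SD, n = 3; limma usage test, adjusted p = 0.00262), and C53B4.3 its first from 48.37 ± 5.11 to 84.08 ± 1.12% (adjusted p = 4.53e-05). Isoform levels are estimates, and a change in how fragments were assigned may add to these 57.

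With 10 splits of the 6 libraries no share under 0.05 can be reached. The real split called 1286 genes and the highest other 7, for transcripts 980 and 13, for lists 20 and 18, and for transcript usage 78 and 36, so in each case 1 split, the real one, gave as many. Each other split holds both treatments within its groups. Treatment differences then enlarge the spread, so its counts do not measure how many calls arise without an effect.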
